A study of Mus musculus with 64 samples.

How the data were processed

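The series holds 64 arrays of total RNA from brain, liver, spleen and thymus of 16 male mice aged 21 weeks. Per the labels, RNA was extracted with Trizol, cleaned on QIAGEN RNeasy midi columns and checked on a gel, and MessageAmp reagents of Ambion gave the biotin-labelled cRNA that was put on the arrays. The submitters' processing notes name GenomeStudio 2011.1. The first deposited table gives a raw signal intensity per probe, on a linear scale with the background not subtracted, per the file headers and values. Beside each intensity it gives the deposited detection p-value of the probe, set against the negative control beads of the array. A second table gives the deposited normalized intensity, which the authors had subtracted for background and brought to nearly the same distribution on all arrays. No depth in counts exists for arrays, and the number of arrays limits the precision. The slide of each array, the genome build and the sequence of each probe's target are not given in the sources used here.

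The labels place the mice in 4 sets of 4: wild types and Hmgn2 knockouts with the strain label C57BL/6, called cohort 1 here, and wild types and Hmgn1 Hmgn2 double knockouts with the strain label C57BL/6J, called cohort 2 here. Each mouse gave 1 array per organ. Every comparison set a mutant against the wild types of its own cohort in the same organ, 4 arrays against 4. The replicate numbers were not used as pairs in the main test: in none of the 8 comparisons did every pair of equal number correlate above 0.1 after removal of the group means. Single pairs did, at up to r = 0.648 in the spleen of cohort 1, so a shared structure in some organs is not ruled out.

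Raw intensities were corrected and normalized within each organ with the neqc function of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, adds an offset of 16, applies quantile normalization and gives log2 values. A probe was tested where its detection p was under 0.01 on at least 4 of the 16 arrays of the organ. Of several probes of 1 gene, the probe with the highest mean was used. This left 9157 genes in the brain, 7647 in the liver, 9237 in the spleen and 9041 in the thymus. Of the 25697 probes, 1719 had no gene and were left out. Symbols follow the RefSeq gene table of assembly GRCm38.p6, which also gave the order of genes along chromosomes.

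The test was limma's moderated test on the 16 arrays of an organ with 4 group means, adjusted by the Benjamini-Hochberg method over the genes tested and read at an adjusted p under 0.05. The same fit tested whether the change in the double knockout differs from the change in the Hmgn2 knockout. A further limma fit over all 64 arrays and 6535 genes detected in every organ took the mouse as a random block, with an estimated correlation of 0.0348 between arrays of a mouse. It tested the mean change over the 4 organs and, by an F test, whether the change differs between organs. Errors given as ± after a log2 fold change are the standard errors of limma, with n = 4 arrays in each group, unless SD is written. Where a mutant or wild-type group lay below detection, the fold change depends on the offset.

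In all, 48 gene lists were fixed before the data were examined, of which those with at least 5 measured members were tested in each organ they concern. The test was camera with a preset correlation of 0.01, repeated with a correlation estimated from the data, with adjustment over the lists of that comparison. The fry test was run beside it, which asks whether the genes of a list move on balance in 1 direction. Of the 1283 words in the lists, 1102 matched a gene on the array by symbol or by an unambiguous synonym, a matching rule tightened after the files were read.

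Genes named in the text followed a rule fixed before the data were examined. It took Hmgn1, Hmgn2, Hmgn3 and Hmgn5, the up to 8 largest increases and 8 largest decreases past the threshold in each comparison, and the 5 smallest p-values where fewer than 5 genes passed. It also took up to 4 members of each list called by camera, genes called in at least 3 organs of a mutant, the 5 smallest p-values for differences between mutants or organs, and the 5 largest increases and decreases of the average over organs. A gene named outside the rule is said to have been chosen after its values were seen.

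Alternatives changed the background correction, the scaling between arrays, the arrays normalized together, the source of the values, the filter, the choice of probe, the arrays in the fit, the array weights, the variance prior, the replicate numbers as a block and the mouse block, and left out each array in turn. Settings that left out the 2 spleen libraries with an Hmgn2 level against their labels, or the arrays outside Tukey's fence of 1.5 interquartile ranges in their correlation with other arrays of the organ, were chosen after seeing the data. Lists without the arrays outside the fence, or without arrays that stood apart in a list, were tested with the preset correlation only. The fit was tested on simulated data with 100 genes raised or lowered at each size. At a planted log2 change of 1, between 87 and 99 percent of the genes were recovered, and at 0.5 between 27 and 48 percent, with 3 to 9 false calls. The simulated values were normal and independent between genes, with no outlying array. More genes were changed than passed in most real comparisons, so recovery in the real data can be lower.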

Results

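The arrays measured RNA in the brain, liver, spleen and thymus of 4 wild types and 4 Hmgn2 knockouts in cohort 1 and of 4 wild types and 4 Hmgn1 Hmgn2 double knockouts in cohort 2. HMGN1 and HMGN2 are small proteins that bind nucleosomes and shape chromatin. An array detected between 9550 and 13411 probes, with 9550 to 10745 in the liver and 12138 to 13411 in the spleen. The 95th percentile of the raw signal ran from 678.1 to 1547 over all arrays. In the thymus it was 806.8 to 933.4 on the Hmgn2 knockout arrays and 1072 to 1257 on those of their wild types, without overlap.

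Hmgn2, the gene targeted in both mutants, was read by 1 probe. Its log2 signal in wild types was near 10.5 in the brain, 8.8 to 9.0 in the liver and 12.8 to 12.9 in the thymus as group means. In the brain it changed by -5.95 ± 0.11 (adjusted p = 3.68e-17) in the Hmgn2 knockout and by -5.58 ± 0.11 (adjusted p = 1.14e-16) in the double knockout. The changes in the liver were -4.37 ± 0.14 and -4.29 ± 0.14, and those in the thymus were -7.40 ± 0.42 and -6.89 ± 0.42, in the same order. In the spleen, the 4 Hmgn2 knockout arrays lay between 4.49 and 5.14 and the 4 wild-type arrays of cohort 1 between 11.99 and 12.44. In cohort 2 of the spleen, 2 libraries had a level against their labels. The library labelled wild type replicate 4 read 6.33, where the other 3 wild types lay between 11.80 and 12.25. The library labelled double knockout replicate 1 read 12.13, where the other 3 double knockouts lay between 4.28 and 4.83. In the thymus, the 4 double knockout arrays read 4.64, 7.20, 6.78 and 5.05.

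**Figure D1:**
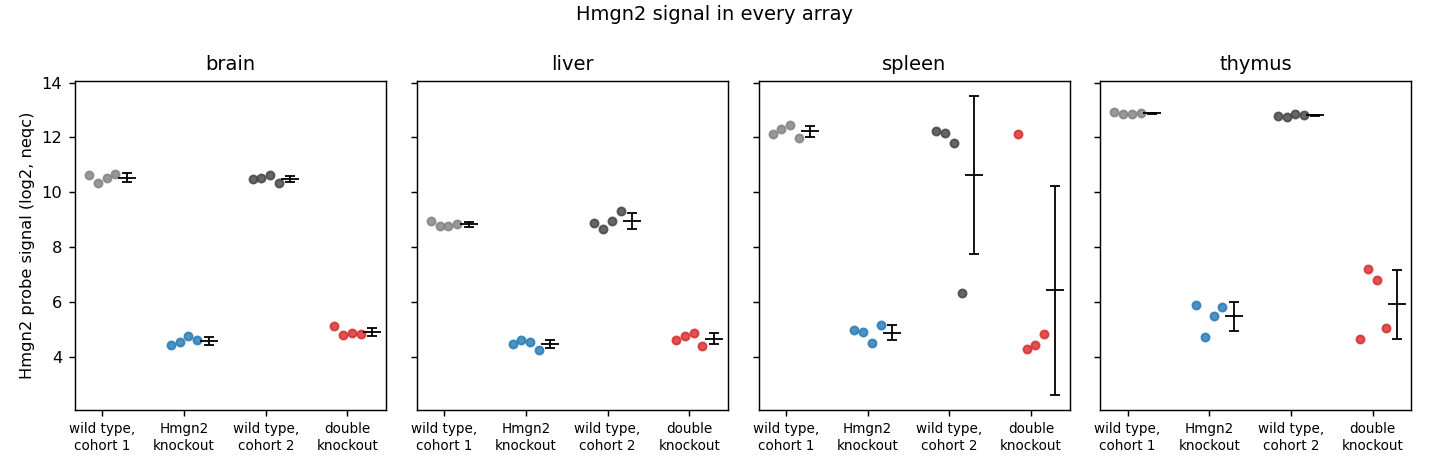
Log2 signal of the Hmgn2 probe on each of the 64 arrays, by organ and group, with the mean and SD of each group (n = 4) beside its points. Every knockout array lies at 7.20 or below except the library labelled double knockout replicate 1 in the spleen, and the library labelled wild type replicate 4 in the spleen lies nearer the knockouts, at 6.33.

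Hmgn1, targeted in the double knockout, was read by 1 probe that stayed bright. Its change in the double knockout was -0.23 ± 0.13 in the brain, -0.013 ± 0.12 in the liver, 0.27 ± 0.14 in the spleen and -0.41 ± 0.086 (adjusted p = 0.0528) in the thymus, none past the threshold. In the thymus it passed in 8 of 19 other settings, and in 0 of those with 1 array left out. A probe outside the deleted part of a gene checks nothing about the deletion, and the position of this probe is not given in the sources used here. Nnt, which is broken in C57BL/6J mice, was detected on 0 arrays, so it does not part the strain labels.

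The first question was what the loss of HMGN2 alone changes in each organ. In the brain, 2 genes fell and 0 rose. They were Hmgn2 and Dhdds, a subunit of the enzyme that makes the lipid carrier of protein glycosylation, which changed by -1.05 ± 0.15 (adjusted p = 0.00911). Cap1, a regulator of actin turnover, was higher by 0.93 ± 0.18 (adjusted p = 0.24) without passing the test. Igfbp2 and Inka2, with the next smallest p-values, changed by -0.50 ± 0.12 and 0.48 ± 0.12 without passing. Of 22 lists tested, cytosolic ribosomal proteins were called by camera as lower (median -0.115, adjusted p = 0.00639, and adjusted p = 0.895 with an estimated correlation). Of its 44 measured members, 0 rose and 0 fell over all genes, and 0 rose and 0 fell adjusted over the list alone, with Rpl38 at -0.35 ± 0.18 and Rps21 at -0.28 ± 0.14. The list was not called with median scaling (adjusted p = 0.205). Without the arrays that correlated less with the other brain arrays, wild type replicate 2 and Hmgn2 knockout replicate 1 among them, it was called at adjusted p = 0.000236, and 7 further lists were called. In all, 259 of 9157 genes had an unadjusted p under 0.05. Left out singly, wild type replicate 3 or 4 brought the count of 2 to 1.

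In the liver of the Hmgn2 knockout, Hmgn2 fell and no other gene passed the test in limma, with 307 of 7647 genes at an unadjusted p under 0.05. The smallest p-values that did not pass belonged to Ndc1 (0.49 ± 0.10), Rdm1 (0.55 ± 0.12), Sp5 (-0.70 ± 0.16) and Fst (0.74 ± 0.18). Camera called 6 of 23 lists, and no call held with an estimated correlation. Endoplasmic reticulum stress genes were lower (median -0.274, adjusted p = 0.00053, and adjusted p = 0.503 with an estimated correlation), with Dnajb9 at -0.60 ± 0.25 and Syvn1 at -0.49 ± 0.20, while Asns of that list was at 0.98 ± 0.41. Cholesterol synthesis genes were lower (median -0.188, adjusted p = 0.00161, and adjusted p = 0.503 with an estimated correlation), with Sqle at -0.49 ± 0.26 and Lss at -0.37 ± 0.16. Type I interferon response genes were lower (median -0.16, adjusted p = 0.0018, and adjusted p = 0.728 with an estimated correlation), with Usp18 at -0.50 ± 0.21 and Isg15 at -0.41 ± 0.20. Acute phase response genes were lower (median -0.281, adjusted p = 0.00127, and adjusted p = 0.728 with an estimated correlation). Lcn2, an iron-sequestering protein of the acute phase, read 8.30 ± 4.12 in the wild types and 5.56 ± 0.47 in the mutants (SD, n = 4), and the large SD shows how far the wild types were from each other. Genes of gluconeogenesis and fasting were higher (median 0.172, adjusted p = 0.00136, and adjusted p = 0.486 with an estimated correlation), with Igfbp1 at 1.33 ± 0.36 and G6pc at 0.57 ± 0.32. Immediate early genes were higher (median 0.133, adjusted p = 0.0473, and adjusted p = 0.503 with an estimated correlation), with Egr1 at 1.72 ± 0.69, and this call was also lost under 3 of the 4 other scalings and without Hmgn2 knockout replicate 2 (adjusted p = 0.359). Over all genes 0 members of the 6 lists passed. Adjusted over the list alone, 3 genes of gluconeogenesis and fasting rose and 0 members of the other 5 lists passed. Without wild type replicate 1 the count of genes was 3, and without Hmgn2 knockout replicate 2, which correlated less with the other liver arrays, it was 2. Without that Hmgn2 knockout array, camera also called 2 lists as higher, with no correlation estimated. They were fatty acid oxidation and PPAR alpha targets, and liver immune and stellate cells (adjusted p = 0.0137 each).

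In the spleen of the Hmgn2 knockout, 0 genes passed the test in limma, and 268 of 9237 had an unadjusted p under 0.05. Hmgn2 itself was at -7.34 ± 1.47 (adjusted p = 0.413), since the 2 libraries of cohort 2 against their labels widened the spread that the groups share. Without those 2 libraries it passed, at -7.33 ± 0.17 (adjusted p = 2.5e-12), and 238 genes had an unadjusted p under 0.05. Cap1 was at 0.88 ± 0.17 (adjusted p = 0.413) and Rimkla at 0.99 ± 0.17 (adjusted p = 0.224), neither past the threshold. Camera called 2 of 22 lists. Neutrophil and granule genes were lower (median -0.42, adjusted p = 0.000816, and adjusted p = 0.971 with an estimated correlation), with 0 of 21 members higher and Csf3r, the receptor of a neutrophil growth factor, at -0.59 ± 0.30. Cytosolic ribosomal proteins were lower (median -0.0933, adjusted p = 0.0328, and adjusted p = 0.971 with an estimated correlation), a call not made with median scaling (adjusted p = 0.644) or without the 2 spleen arrays that correlated least with the others. In both lists 0 members passed over all genes and 0 adjusted over the list alone. Without those 2 arrays, neutrophil and granule genes stayed lower (adjusted p = 1.2e-06), exocrine pancreas (4.4e-09), core histones (0.0131) and cell cycle genes (0.0368) were also called as lower, and mature T cells and natural killer cells as higher (adjusted p = 0.00807 each), a setting in which no correlation was estimated. Without wild type replicate 1, 1 gene passed.

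In the thymus of the Hmgn2 knockout, 1405 of 9041 genes passed the test, 653 higher and 752 lower. Among those that fell were Dhdds (-1.5 ± 0.14, adjusted p = 2.3e-05), Slirp (-1.18 ± 0.10, adjusted p = 1.2e-05), which stabilises mitochondrial RNA, and Selenow (-1.36 ± 0.26, adjusted p = 0.00325), a selenoprotein. Tmsb10, which binds actin monomers, fell with -1.12 ± 0.26, Itgb3bp, a centromere protein, with -1.08 ± 0.20, and Cnot4, a ubiquitin ligase, with -1.05 ± 0.12. Among those that rose were Atp2a2 (1.25 ± 0.41, adjusted p = 0.0477), the calcium pump of the endoplasmic reticulum, Rimkla (1.09 ± 0.15, adjusted p = 0.000476), Cap1 (1.05 ± 0.26, adjusted p = 0.0138), Dkk3 (1.01 ± 0.25, adjusted p = 0.0136) and the long noncoding RNA Tug1 (0.90 ± 0.12, adjusted p = 0.000355). The call of Atp2a2 ended in 12 of 19 other settings, among them median scaling and only the 8 arrays. Of the other HMGN genes, Hmgn3 (-0.56 ± 0.14, adjusted p = 0.0153) and Hmgn1 (-0.34 ± 0.086, adjusted p = 0.0137) fell, and Hmgn5 was at -0.40 ± 0.17 (adjusted p = 0.11).

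Camera called 4 of 24 lists in the Hmgn2 knockout thymus, and fry passed for all 4. In the brain and the spleen fry passed for 0 lists in either mutant. It passed for 0 lists in the liver of the Hmgn2 knockout, 1 in the liver of the double knockout and 2 in the thymus of the double knockout. Core histones fell as a list (median -0.514, adjusted p = 1.89e-13), and the adjusted p = 0.0721 with an estimated correlation. Of its 33 measured genes, 0 rose and 18 fell over all genes, and 1 rose and 27 fell adjusted over the list alone, among them H4c4 (-0.93 ± 0.14), H4c6 (-0.69 ± 0.091) and H3c4 (-0.61 ± 0.086). Genes of oxidative phosphorylation fell as a list (median -0.396, adjusted p = 1.13e-15, and adjusted p = 0.119 with an estimated correlation). Of its 52 measured genes, 0 rose and 31 fell over all genes, and 1 rose and 38 fell adjusted over the list alone, among them Ndufa2 (-0.92 ± 0.11) of complex I, Cox6a1 (-0.78 ± 0.10) of complex IV and Atp5l (-0.85 ± 0.12) of the ATP synthase. Cytosolic ribosomal proteins fell as a list (median -0.285, adjusted p = 6e-09, and adjusted p = 0.269 with an estimated correlation). Of its 44 measured genes, 1 rose and 17 fell over all genes, and 2 rose and 26 fell adjusted over the list alone, among them Rpl30 (-0.79 ± 0.11) and Rps15 (-0.66 ± 0.11). Genes of immature thymocytes rose as a list (median 0.2, adjusted p = 0.00816, and adjusted p = 0.119 with an estimated correlation). Of its 24 measured genes, 4 rose and 0 fell over all genes, and 6 rose and 0 fell adjusted over the list alone, among them Ets2 (0.69 ± 0.10), Themis (0.55 ± 0.13), which tunes T cell receptor signals, and Dntt (0.42 ± 0.11), which adds bases at receptor joints. With median scaling this list was at adjusted p = 0.466, and the split of all called genes was 496 higher and 900 lower. These lists moved on arrays whose raw 95th percentile was below that of every wild-type array of cohort 1. The count was 771 without Hmgn2 knockout replicate 3, 2301 without Hmgn2 knockout replicate 4, 870 without wild type replicate 4 and 336 with only the 8 arrays of the comparison.

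**Figure D2:**
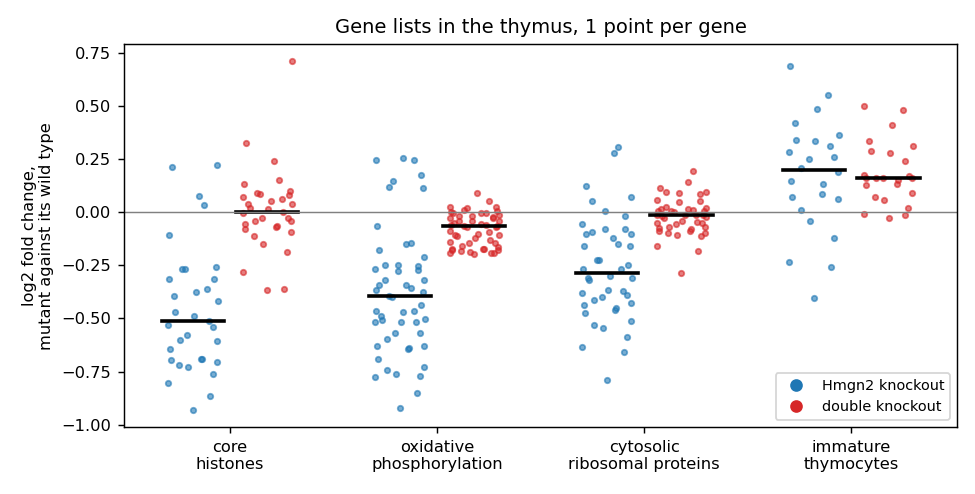
Log2 fold change in the thymus of each measured gene of 4 lists, for the Hmgn2 knockout and the double knockout against their own wild types, with the median as a bar. The median of core histones is -0.514 in the Hmgn2 knockout, and 0.0024 in the double knockout.

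The next question was what the loss of both proteins changes. In the brain of the double knockout 13 genes passed the test, 9 higher and 4 lower. Mrps27 (-2.04 ± 0.23, adjusted p = 0.00016), a protein of the mitochondrial ribosome, Dhdds (-1.22 ± 0.15, adjusted p = 0.000457) and Hsd17b11 (-0.84 ± 0.16), a lipid droplet enzyme, fell beside Hmgn2. Dao (2.77 ± 0.41, adjusted p = 0.00389), which oxidises D-amino acids, Ccng2 (1.82 ± 0.19, adjusted p = 0.000105), an atypical cyclin, Trim11 (1.73 ± 0.33, adjusted p = 0.0394), a ubiquitin ligase, and Psmd8 (0.80 ± 0.14, adjusted p = 0.0153), a part of the proteasome, rose. Zfp940 (0.99 ± 0.12), Sgsm1 (0.91 ± 0.13), Ehd1 (0.84 ± 0.15) and Lgals4 (0.66 ± 0.12) rose as well. Another probe of Lgals4 was at 0.15, while those of Dhdds and Hsd17b11 were at -0.99 and -0.859. Camera called 2 of 22 lists. Type I interferon response genes were lower (median -0.162, adjusted p = 0.000741, and adjusted p = 0.328 with an estimated correlation), with Ifit3 at -0.40 ± 0.15 and Usp18 at -0.32 ± 0.13. Skeletal muscle genes were higher (median 0.228, adjusted p = 0.0106, and adjusted p = 0.453 with an estimated correlation). Its members in the brain included Pvalb, a marker of fast-spiking neurons, at 0.29 ± 0.15, and Eno3 at 0.38 ± 0.14. In both lists 0 members passed over all genes and 0 adjusted over the list alone. Striatum and microglia lists were lower without passing (adjusted p = 0.0548 and 0.0872), and without the arrays outside the fence both were called as lower (0.0349 and 0.0234), as were cytosolic ribosomal proteins (0.00688), with no correlation estimated. In all, 596 genes had an unadjusted p under 0.05. Calls that ended in most other settings were those of Hsd17b11 (14 of 20), Lgals4 (12 of 20) and Trim11 (11 of 19). With array weights the count was 339, and leaving out a double knockout brought it to 8, 7, 8 and 8 for replicates 1, 2, 3 and 4.

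In the liver of the double knockout 24 genes passed, 13 higher and 11 lower, and 703 had an unadjusted p under 0.05. The double knockout arrays detected 9550 to 9938 probes and those of their wild types 10037 to 10407, without overlap. Mrps27 (-1.98 ± 0.17, adjusted p = 5.07e-06), Vldlr (-1.27 ± 0.23, adjusted p = 0.0133), a lipoprotein receptor, Igtp (-1.11 ± 0.17, adjusted p = 0.00384), an interferon-induced GTPase, and Asgr2 (-0.93 ± 0.17, adjusted p = 0.0191), a subunit of the asialoglycoprotein receptor, fell. Tiam2 (-1.08 ± 0.20), Zfp30 (-0.82 ± 0.13) and Pebp1 (-0.75 ± 0.14) fell as well. Xlr4a (2.36 ± 0.40, adjusted p = 0.00954), Ccng2 (1.5 ± 0.22, adjusted p = 0.00384), Trim11 (1.48 ± 0.24, adjusted p = 0.00846), Dct (1.42 ± 0.24, adjusted p = 0.00978), a melanin enzyme, and Dio1 (1.12 ± 0.23, adjusted p = 0.0446), which activates thyroid hormone, rose, with Ulk2 (1.0 ± 0.15), Zfp39 (0.99 ± 0.17) and Psmd8 (0.81 ± 0.10). Male-biased targets of growth hormone rose as a list (median 0.297, adjusted p = 3.37e-13), and the call held with an estimated correlation (adjusted p = 0.0143). Of its 26 measured genes, 2 rose and 0 fell over all genes, and 9 rose and 0 fell adjusted over the list alone. Mup20 (1.12 ± 0.15, adjusted p = 0.00128) and Mup21 (0.83 ± 0.10, adjusted p = 0.000319), urinary proteins that carry pheromones, rose, and Mup5 was at 0.72 ± 0.15 (adjusted p = 0.0623) and Cyp7b1, a steroid hydroxylase, at 0.64 ± 0.14 (adjusted p = 0.0936). Mup20 averaged 12.95 in the wild types of cohort 1, 11.88 in those of cohort 2 and 13.01 in the double knockouts. Mup21 was otherwise, at 13.19, 13.03 and 13.86 in the same order. Double knockout replicate 3 stood apart from its group at Mup20 and Mup5. Core histones were higher (median 0.173, adjusted p = 0.00533, and adjusted p = 0.884 with an estimated correlation), with H4c8 at 0.74 ± 0.17, and 0 of its genes passed over all genes and 1 rose adjusted over the list alone. Fatty acid synthesis genes were lower (median -0.243, adjusted p = 0.00189, and adjusted p = 0.884 with an estimated correlation), with Me1 at -0.56 ± 0.21 and Acaca at -0.37 ± 0.12, and 0 passed over all genes and 0 adjusted over the list alone. Liver immune and stellate cell genes were lower without passing (adjusted p = 0.0526), and were called without double knockout replicate 4, which stood apart in this list (adjusted p = 0.000332). The calls of Dio1 and Tiam2 ended in 13 of 20 and 12 of 19 other settings. Without double knockout replicate 3 the count of genes was 11, and with array weights it was 52.

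In the spleen of the double knockout, 0 genes passed the test in limma on all 16 arrays, and 987 had an unadjusted p under 0.05. Npm3-ps1 and Sct had the smallest p-values, at 1.25 ± 0.19 (adjusted p = 0.0559) and 0.84 ± 0.15 (adjusted p = 0.17). Without the library labelled wild type replicate 4 and the library labelled double knockout replicate 1, 3 genes rose and 4 fell. Hmgn2 (-7.56 ± 0.20), Mrps27 (-1.84 ± 0.19), Naip5 (-1.83 ± 0.27), a sensor of bacterial flagellin, and P2ry12 (-1.32 ± 0.19), a receptor for ADP, fell. Ccng2 (1.77 ± 0.24), Psmd8 (1.09 ± 0.13) and Ly6k (1.22 ± 0.20) rose, and Naip5, P2ry12 and Ly6k were chosen after their values were seen. Camera called 4 of 22 lists on all 16 arrays, each as higher and none with an estimated correlation. Of 52 genes of oxidative phosphorylation, 50 were higher (median 0.571, adjusted p = 7.89e-22, and adjusted p = 0.706 with an estimated correlation), with Ndufa5 at 1.04 ± 0.29. Core histones (median 0.415, adjusted p = 3.01e-09, and adjusted p = 0.706 with an estimated correlation) and cytosolic ribosomal proteins (median 0.35, adjusted p = 9.22e-13, and adjusted p = 0.706 with an estimated correlation) were higher, with H2ac7 at 1.29 ± 0.45 and Rpl31 at 0.76 ± 0.21. Neutrophil and granule genes were higher (median 0.9, adjusted p = 0.000298, and adjusted p = 0.785 with an estimated correlation), with S100a8 at 1.14 ± 0.36. Over all genes 0 members of these lists passed, and adjusted over the list alone 27 genes of oxidative phosphorylation and 3 ribosomal proteins rose. Without the 2 libraries against their labels the 4 calls remained, and plasma cells and immunoglobulins were called as higher (adjusted p = 0.0186). With an estimated correlation none of the 5 was called, the smallest adjusted p being 0.601. Wild type replicate 3 of cohort 2 correlated least with the other spleen arrays, at a median r of 0.938, and without it and the other arrays outside the fence the 4 calls remained and B cells and exocrine pancreas were called as lower (adjusted p = 0.0365 and 1.43e-05), with no correlation estimated. The exocrine pancreas list was not called with double knockout replicate 4 alone left out (adjusted p = 0.934), and pointed up without the 2 libraries against their labels (adjusted p = 0.31). Leaving out wild type replicate 1 or the library labelled wild type replicate 4 gave 1 gene each.

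In the thymus of the double knockout 21 genes passed, 9 higher and 12 lower, and 813 had an unadjusted p under 0.05. Mrps27 (-1.60 ± 0.14, adjusted p = 5.64e-06), Pttg1 (-1.22 ± 0.12, adjusted p = 1.86e-05), also called securin, Dhdds (-1.09 ± 0.14, adjusted p = 0.000833) and Ublcp1 (-0.96 ± 0.10, adjusted p = 0.000107), a phosphatase of the proteasome, fell with Fbxo27 (-1.27 ± 0.17), Gm12253 (-0.99 ± 0.13) and Tlr6 (-0.86 ± 0.14), a receptor for bacterial lipopeptides. Ccng2 (2.18 ± 0.17, adjusted p = 1.42e-06), Cbr3 (1.49 ± 0.094, adjusted p = 8.74e-08), a carbonyl reductase, Psmd8 (0.80 ± 0.12, adjusted p = 0.00355) and Cd163 (0.87 ± 0.15, adjusted p = 0.0133), a macrophage receptor for haemoglobin, rose with Zfp420 (0.96 ± 0.14), Zfp39 (0.77 ± 0.13), Rell1 (0.74 ± 0.13) and Plekhf1 (0.73 ± 0.13). Genes of immature thymocytes rose as a list (median 0.162, adjusted p = 5.35e-05), the 1 call of 12 that held with an estimated correlation (adjusted p = 0.0426). Of its 24 measured genes 21 were higher, with Dtx1 at 0.50 ± 0.14 and Rag2 at 0.31 ± 0.12, and 0 passed over all genes and 0 adjusted over the list alone. Cell cycle genes were higher (median 0.144, adjusted p = 0.0013, and adjusted p = 0.213 with an estimated correlation), with Kif11 at 0.31 ± 0.12. Another probe of Plekhf1 was at 0.23, while those of Cbr3 and Dhdds were at 1.21 and -0.804. With array weights the count of genes was 176, with only the 8 arrays 47, and without background correction 42.

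The other 10 lists called in the thymus of the double knockout were lower, mostly markers of cells other than immature thymocytes. The double knockout thymus arrays also detected fewer probes, 11664 to 12505 against 12600 to 13096 on those of their wild types, without overlap. Type I interferon response genes (median -0.247, adjusted p = 8.99e-08, and adjusted p = 0.15 with an estimated correlation) included Oas1g at -0.53 ± 0.13 and Usp18 at -0.43 ± 0.12, and fry passed for this list. Neutrophil and granule genes (median -0.806, adjusted p = 4.25e-06, and adjusted p = 0.213 with an estimated correlation) included Mpo at -0.92 ± 0.27. Macrophage and dendritic cell genes (median -0.201, adjusted p = 0.00109, and adjusted p = 0.231 with an estimated correlation) included Timd4 at -1.0 ± 0.26, while Cd163 of the same list rose. Natural killer and cytotoxic cell genes (median -0.301, adjusted p = 0.00176, and adjusted p = 0.213 with an estimated correlation) included Ccl5 at -0.71 ± 0.20. Mature thymocyte genes (median -0.152, adjusted p = 0.00176, and adjusted p = 0.231 with an estimated correlation) included Slfn1 at -0.68 ± 0.20 and Ly6c1 at -0.50 ± 0.10, and without double knockout replicate 2 and wild type replicate 4, which stood apart in this list, it was not called (adjusted p = 0.109). B cell genes (median -0.164, adjusted p = 0.00946, and adjusted p = 0.305 with an estimated correlation) included Fcrla at -0.40 ± 0.17. Stroma and endothelium genes (median -0.194, adjusted p = 0.00456, and adjusted p = 0.213 with an estimated correlation) included Lum at -0.56 ± 0.13. Thymic epithelium genes (median -0.176, adjusted p = 0.00206, and adjusted p = 0.213 with an estimated correlation) included Krt14 at -0.53 ± 0.17. Endoplasmic reticulum stress genes (median -0.1, adjusted p = 0.0484, and adjusted p = 0.218 with an estimated correlation) included Xbp1 at -0.23 ± 0.084. Genes of oxidative phosphorylation (median -0.0658, adjusted p = 0.00176, and adjusted p = 0.416 with an estimated correlation) included Ndufs8 at -0.20 ± 0.093. Of these 10 lists 0 members fell over all genes. Adjusted over the list alone, 3 interferon response genes, 3 mature thymocyte genes, 2 natural killer genes, 2 macrophage genes, 1 neutrophil gene and 1 stroma gene fell, and 1 natural killer gene and 1 macrophage gene rose.

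Mrps27, Ccng2 and Psmd8, with Hmgn2, passed in the same direction in 3 organs of the double knockout, and in the Hmgn2 knockout Hmgn2 alone did. In the spleen, where they did not pass on all 16 arrays, Mrps27 was at -0.93 ± 0.42, Ccng2 at 0.57 ± 0.56 and Psmd8 at 0.71 ± 0.20. For each of these 3 genes, the library labelled wild type replicate 4 was nearer the mean of the other 3 double knockouts, and the library labelled double knockout replicate 1 was nearer the mean of the other 3 wild types.

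**Figure D3:**
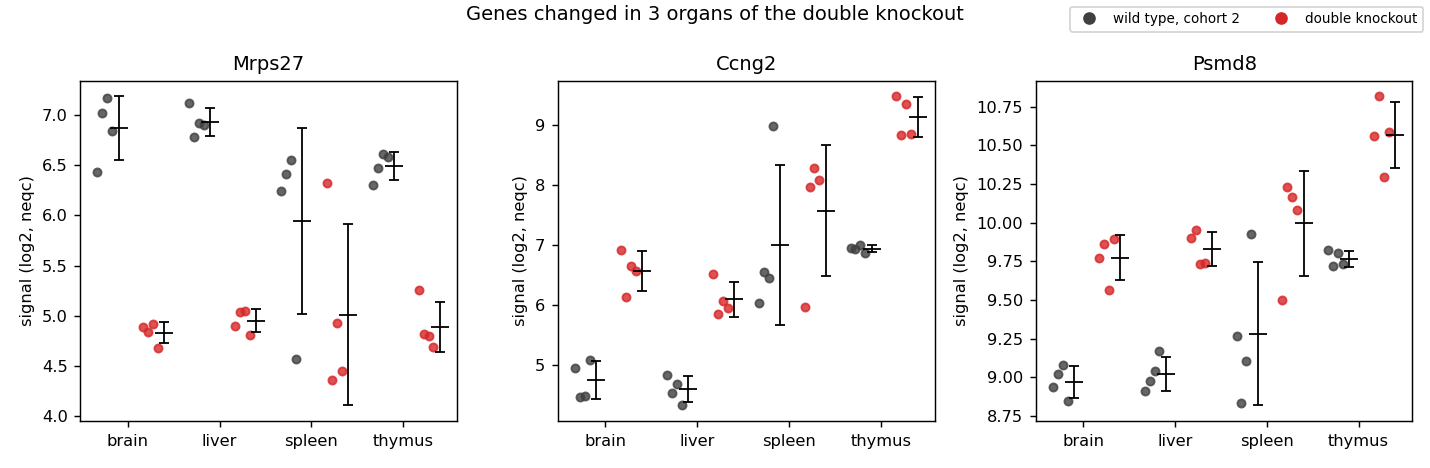
Log2 signal of Mrps27, Ccng2 and Psmd8 on each array of cohort 2 by organ, with the mean and SD of each group (n = 4) beside its points. The groups do not overlap in brain, liver and thymus, and in the spleen 1 library of each label lies nearer the other label.

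Whether the double knockout differs from the Hmgn2 knockout was tested as a difference of the 2 changes. It passed for 1 gene in the brain, 2 in the liver, 0 in the spleen and 157 in the thymus, of which 42 were lower and the others higher. In the brain it was Ccng2, at 1.80 ± 0.27 (adjusted p = 0.0313), and in the liver Mrps27 and Psmd8, at -2.05 ± 0.24 (adjusted p = 0.000965) and 0.83 ± 0.14 (adjusted p = 0.0461). The call of Ccng2 in the brain ended in 14 of 21 other settings and that of Psmd8 in the liver in 14 of 21, most of them with 1 array left out. In the thymus the smallest p-values were those of Cbr3 (2.02 ± 0.13), Ccng2 (2.24 ± 0.24), Mrps27 (-1.55 ± 0.20), Mrps12 (1.09 ± 0.14) and Slirp (1.09 ± 0.15). Slirp changed by -1.18 in the Hmgn2 knockout and was at -0.089 in the double knockout, and Cbr3 was at -0.52 and 1.49. In limma, 438 genes in the brain, 500 in the liver, 749 in the spleen and 1537 in the thymus had an unadjusted p under 0.05. The thymus count was 898 without Hmgn2 knockout replicate 4 and 30 without wild type replicate 1 of cohort 2. A difference between the cohorts that acts on the mutants or on the wild types of 1 cohort is not separated by this test: Ccng2 in the brain averaged 7.55 and 7.56 in the wild types and mutants of cohort 1 and 4.75 and 6.57 in those of cohort 2, and Psmd8 in the liver 9.91, 9.89, 9.02 and 9.83 in the same order.

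Across genes, which are not independent replicates, the changes of the 2 mutants correlated with r = -0.0366 in the brain, -0.0357 in the liver, -0.166 in the spleen and 0.158 in the thymus, Hmgn2 left out. Each lay inside the range under permuted genotype labels, which in the thymus was -0.415 to 0.427. Dhdds and Hmgn2 fell in both mutants in the brain. In the thymus 4 genes rose in both mutants (Ankle2, Zfp420, Cd163 and Zfp39), where 0.65 would be expected of independent calls. At each of the 4, the wild types of cohort 1 lay nearer the double knockouts than the wild types of cohort 2. Cd163 averaged 7.34, 6.49 and 7.36 in the wild types of cohort 1, those of cohort 2 and the double knockouts. The overlap is therefore not shown to be a shared effect of losing HMGN2. Dhdds and Sostdc1 fell in both mutants, beside Hmgn2, which is lost in both by design. Cbr3 was called in both mutants in opposite directions. Ankle2 and Sostdc1 were chosen after their values were seen.

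Averaged over the 4 organs, 5 of 6535 genes passed in the Hmgn2 knockout, 1 higher and 4 lower. Beside Hmgn2, Dhdds (-0.96 ± 0.11, adjusted p = 1.5e-08) and the cold-inducible RNA-binding proteins Cirbp (-0.45 ± 0.092, adjusted p = 0.0164) and Rbm3 (-0.48 ± 0.11, adjusted p = 0.0451) fell, and Cap1 (0.90 ± 0.12, adjusted p = 1.1e-06) rose, each in the same direction in 4 of 4 organs. The call of Rbm3 ended in 8 of 15 other settings and that of Cirbp in 4 of 15, mostly with 1 mouse left out. With 1 mouse left out the count of 5 was between 3 and 11. In limma, 0 genes passed the test for a change that differs between organs in the Hmgn2 knockout, with 719 at an unadjusted p under 0.05. The number that passed was 27 without Hmgn2 knockout mouse 1 and 25 without the filter. In the double knockout 32 genes passed on average, 20 higher and 12 lower, and between 20 and 38 with 1 mouse left out. Mrps27 (-1.64 ± 0.14, adjusted p = 1.78e-12), Dhdds (-0.85 ± 0.11, adjusted p = 1.53e-07), Hsd17b11 (-0.78 ± 0.12, adjusted p = 4.52e-05) and Ublcp1 (-0.61 ± 0.075, adjusted p = 4.61e-08) fell, and Ccng2 (1.52 ± 0.18, adjusted p = 4.61e-08), Trim11 (1.45 ± 0.28, adjusted p = 0.0016), Psmd8 (0.78 ± 0.075, adjusted p = 2.4e-11) and Zfp420 (0.64 ± 0.11, adjusted p = 0.000116) rose, each in the same direction in 4 of 4 organs. Xlr4a (0.81 ± 0.18, adjusted p = 0.00958) rose on average through the liver, and was at 0.0086 in the spleen. A change that differs between organs passed for 17 genes of the double knockout. Pttg1 (adjusted p = 1.86e-10) was at -1.22 in the thymus and 0.70 in the liver. In the liver the wild types of cohort 2 averaged 4.255 for Pttg1, near the 4.202 to 4.259 of the undetected Nnt probes. Cbr3 (adjusted p = 4.02e-07) was at 1.49 in the thymus and -0.28 in the liver. Igtp (adjusted p = 4.61e-05) was at -1.11 in the liver and 0.31 in the brain. Ulk2 (adjusted p = 0.000667) was at 1.0 in the liver and -0.35 in the spleen, and Npm3-ps1 (adjusted p = 0.00668) at 1.25 in the spleen. The spleen values hold the 2 libraries with an Hmgn2 level against their labels, without which 44 genes passed on average and 19 differed between organs in the double knockout. Wild-type mouse 1 of cohort 2 moved the count of 17 most when left out, upward, while wild-type mouse 3 of cohort 2 brought it to 5 and mice 1, 2 and 3 of the double knockouts to 6, 6 and 5.

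The genes called in the double knockout lay close together on some chromosomes, a feature looked for after their values were seen. Hmgn2 left out, 45 genes were called in at least 1 organ, of which 11 lie on chromosome 7, 8 on chromosome 11 and 8 on chromosome 5. Fbxo27, Mrps12, Nfkbib, Lgals4, Psmd8, Zfp30, Zfp940 and Zfp420 lie within 25 tested genes of each other on chromosome 7, and Igtp, Gm12253, Zfp39 and Trim11 do on chromosome 11. There were 40 pairs of called genes within 25 tested genes of each other, and 1000 random sets of as many genes gave a median of 4 and at most 13. The wild types of cohort 1 were nearer the double knockouts than the wild types of cohort 2 at 43 of 55 calls. Ccng2 in the thymus averaged 9.49 in the wild types of cohort 1, 6.94 in those of cohort 2 and 9.12 in the double knockouts. Mrps27 was otherwise, at 6.48, 6.49 and 4.89 in the same order, and so were Dhdds and Cbr3.

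**Figure D4:**
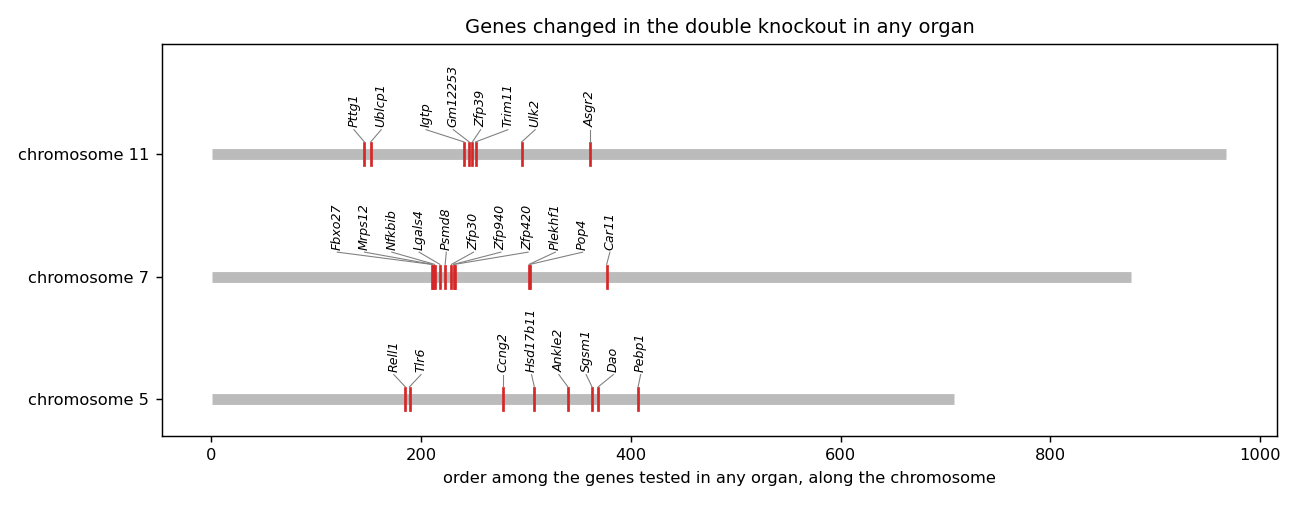
Genes called in the double knockout in any organ, drawn as red marks in their order among the genes tested in any organ along chromosomes 5, 7 and 11 of assembly GRCm38.p6. The grey bar spans the 708, 877 and 968 tested genes of chromosomes 5, 7 and 11, and 8 of the 11 marks on chromosome 7 lie together.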

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

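The 3 patterns weighed below were chosen after the result was seen, and so were the tests of exchanged labels, of mixed RNA, of an axis shared with other organs, of the slope between mutants, of neighbouring calls and of the distance to the wild types of cohort 1. The tests of raw signal and of second probes were set before their results were seen, and the range that decides the test of raw signal was added afterwards without changing its outcome.

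The 2 spleen libraries of cohort 2 with an Hmgn2 level against their labels stood apart from the others in their groups, the library labelled wild type at Hmgn2 and Mrps27 and the library labelled double knockout at Hmgn2, Ccng2 and H2ac7. A mixture of RNA of both genotypes in each library is argued against by the Hmgn2 signal, which implies 1.33 percent wild-type RNA in the library labelled wild type and 104 percent in the library labelled double knockout. Exchanged labels were weighed on 17 other genes called in the double knockout in other organs. These differed by more than 0.5 log2 between the other 6 spleen libraries by label, a gap chosen after seeing the pattern. The library labelled wild type was nearer the double knockouts at 88.2 percent of them, and the library labelled double knockout nearer the wild types at 76.5 percent, which goes with an exchange. The other 6 libraries were toward the other label at 35.3 percent at most. That share is no fair baseline, since these 6 libraries also chose the genes. An exchange of the mice themselves is argued against by their other organs, where Hmgn2 read as labelled: 10.34 in the brain, 9.31 in the liver and 12.81 in the thymus of wild-type mouse 4, and 5.11, 4.59 and 4.64 in double knockout mouse 1. The number of probes detected ran with the labels as given. It was 12770 in the library labelled wild type replicate 4, within the 12692 to 13100 of that label. It was 12537 in the library labelled double knockout replicate 1, within the 12138 to 12652 of that label. At Hmgn2, the targeted gene, both libraries read nearer the other genotype, which argues against their labels as given, while the probe counts do not. Whether the 2 were exchanged with each other, and if so at the spleen sample, its RNA or the array, stays open. No biological explanation was tested, and the labels were kept as given.

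Lower array signal, for the many genes called in the Hmgn2 knockout thymus, was tested on the 8 thymus arrays of cohort 2. Centred on their groups, the score of these genes and the raw 95th percentile gave Pearson r = -0.42 (permutation p = 0.347) and Spearman rho = -0.643 (permutation p = 0.0799). Pearson r was -0.453 without the 2 farthest arrays and between -0.563 and -0.266 with each array left out. By the limit set beforehand these values argue against lower signal. However, the raw 95th percentile of these 8 arrays was 1118 to 1547 and never reached the 806.8 to 933.4 of the Hmgn2 knockout arrays. The test therefore cannot decide about signal that low, and lower signal stays open. Loss of HMGN2 with the same effect whether or not HMGN1 is present is argued against by the double knockout thymus, whose changes had a slope of 0.141 on those of the Hmgn2 knockout over 1404 called genes (0.109 to 0.187 with an array left out). Of these genes 989 (70.4 percent) nevertheless lay in the same direction, with medians in the double knockout of -0.0543 for those that fell and 0.0858 for those that rose, so a small shared part and an effect that the loss of HMGN1 offsets stay open. Across genes, the thymus change correlated with the deviation of the 6 arrays standing apart in other organs at a median absolute r of 0.38, against 0.0676 for 42 other arrays, but the 6 were split: r was 0.6, 0.599 and 0.659 for wild type replicate 2 and Hmgn2 knockout replicate 1 in the brain and wild type replicate 3 of cohort 2 in the spleen, and -0.162, 0.00586 and -0.0432 for double knockout replicate 1 in the brain, Hmgn2 knockout replicate 2 in the liver and Hmgn2 knockout replicate 3 in the spleen. A handling difference between the thymus sets of cohort 1 may therefore account for part of these calls, and it cannot be parted from genotype with 1 set of arrays per genotype.

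The genes called in the double knockout may lie in blocks of the genome that differ in strain origin between the 2 groups of cohort 2, since 40 pairs of called genes lay within 25 tested genes of each other, where random sets gave a median of 4. Loss of HMGN1 and HMGN2 as the cause of most of these calls is argued against, since at 78.2 percent of 55 calls the wild types of cohort 1, which have both genes, were nearer the double knockouts. A sequence variant under single probes cannot be told apart for all of them: another probe changed the same way by at least 50 percent as much at 81.8 percent of the 11 calls that have one. That value is past the 75 percent set beforehand for arguing against a variant. It was left as undecided after it was seen, since 9 of 11 is not beyond its spread. Also, the other 44 calls rest on 1 probe. The exceptions among the 11 were Lgals4 in the brain (other probe at 0.15) and Plekhf1 in the thymus (0.23). Calls at which the wild types of cohort 1 lay with those of cohort 2, such as Mrps27, Dhdds and Cbr3, stay open to an effect of the targeted loci. There the distance to the wild types of cohort 1 cannot part such an effect from a strain block carried by the double knockouts alone. Dhdds lies beside Hmgn2 and Cbr3 beside Hmgn1, whereas Mrps27 lies on chromosome 13, beside neither.

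The change differed between the 2 mutants, by the test of the difference itself, for Ccng2 in the brain (1.80), Mrps27 (-2.05) and Psmd8 (0.83) in the liver, and Mrps27 (-1.55), Mrps12 (1.09), Slirp (1.09), Cbr3 (2.02) and Ccng2 (2.24) in the thymus, as log2 differences. The counts of such genes were 1 in the brain, 2 in the liver and 157 in the thymus. Other groupings of the arrays, the real one included, gave as many genes in 11 of 100 in the brain and 8 of 100 in the liver. Ccng2 in the brain and Psmd8 in the liver lost the call in most other settings. Their lowest group means were those of the wild types of cohort 2. The change differed between organs in the double knockout for 17 genes, among them Pttg1 (adjusted p = 1.86e-10), Cbr3 (4.02e-07), Igtp (4.61e-05), Ulk2 (0.000667) and Npm3-ps1 (0.00668).

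In groups of 4 arrays, 534 sets of values were screened for an array far from the other 3, and 38 (7.12 percent) had a gap to the nearest array above Dixon's limit, where chance gives about 1 in 20. The gap is given in parentheses as a share of the whole range of the group. In the brain, wild types of cohort 1 gave Rpl38 in replicate 2 (0.844) and Rps21 in replicate 2 (0.872). Among the Hmgn2 knockouts of the brain there were Dhdds in replicate 1 (0.878) and Rps21 in replicate 1 (0.882). The wild types of cohort 2 of the brain had Dao in replicate 4 (0.953), Dhdds in replicate 2 (0.847) and Lgals4 in replicate 1 (0.876). In the brain, double knockouts gave Hsd17b11 in replicate 4 (0.87). Among the wild types of cohort 1 of the liver there were Irs2 in replicate 1 (0.831). The Hmgn2 knockouts of the liver had Hmgn3 in replicate 4 (0.898) and Sqle in replicate 4 (0.838). In the liver, double knockouts gave Mup20 in replicate 3 (0.87), Mup5 in replicate 3 (0.92) and the 95th percentile of the raw signal in replicate 3 (0.938). Among the wild types of cohort 1 of the spleen there were Rps14 in replicate 1 (0.895). The Hmgn2 knockouts of the spleen had Rps14 in replicate 3 (0.892) and Rps19 in replicate 3 (0.913). In the spleen, libraries labelled wild type of cohort 2 gave H2ac7 in replicate 3 (0.857), Hmgn1 in replicate 3 (0.934), Hmgn2 in replicate 4 (0.923) and Mrps27 in replicate 4 (0.842). Among the libraries labelled double knockout of the spleen there were Ccng2 in replicate 1 (0.87), H2ac7 in replicate 1 (0.926) and Hmgn2 in replicate 1 (0.93). The Hmgn2 knockouts of the thymus had Arpp21 in replicate 3 (0.835) and Rimkla in replicate 3 (0.831). In the thymus, wild types of cohort 2 gave Cbr3 in replicate 3 (0.913), Hyou1 in replicate 4 (0.895), Klrk1 in replicate 4 (0.92), Lcn2 in replicate 4 (0.846) and the median raw signal in replicate 1 (0.835). Among the double knockouts of the thymus there were Csn2 in replicate 2 (0.85), Fcrla in replicate 2 (0.891), Notch3 in replicate 2 (0.845), Oas2 in replicate 4 (0.843), Prss16 in replicate 3 (0.85), Pttg1 in replicate 3 (0.837) and the 95th percentile of the raw signal in replicate 3 (0.846).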

How the results depend on the processing

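Settings that left out libraries for their Hmgn2 level or their correlation were chosen after seeing the data, and all others were planned. The slide block was not run, since no slide is named. Of 5167 values of named genes under other settings, 4891 had the same outcome, called or not called, 221 lost a call, 55 gained one and 0 reversed. Of the 4891, 24 differed in sign with no call under either setting. Counts that moved by more than 1.5 times follow, and the cause was not tested except where fewer probes or arrays enter. Without background correction the counts became brain difference 0, thymus double knockout 42, thymus difference 307, Hmgn2 knockout organ difference 1 and double knockout organ difference 50. With median scaling the counts became brain difference 2, liver difference 1 and thymus double knockout 34. On the deposited normalized values the counts became brain difference 0 and double knockout organ difference 43. Normalized over 64 arrays the counts became spleen double knockout 1. With no filter the counts became brain difference 0, Hmgn2 knockout organ difference 25 and double knockout organ difference 65. With probes detected on all 16 arrays the counts became brain Hmgn2 knockout 1, brain double knockout 5, liver Hmgn2 knockout 0, liver double knockout 13 and spleen double knockout 1. With every probe tested the counts became brain double knockout 20, liver Hmgn2 knockout 2 and spleen double knockout 2. With only the 8 arrays the counts became brain Hmgn2 knockout 1, brain double knockout 20, spleen Hmgn2 knockout 1, thymus Hmgn2 knockout 336 and thymus double knockout 47. With array weights the counts became brain double knockout 339, liver double knockout 52, spleen Hmgn2 knockout 1, spleen double knockout 3 and thymus double knockout 176. With a trend and robust prior the counts became spleen double knockout 1 and thymus double knockout 34. With no mouse block the counts became Hmgn2 knockout average 9. With median scaling the called thymus genes of the Hmgn2 knockout were 496 higher and 900 lower, and those of the liver double knockout 17 and 9. With replicate numbers as a replicate block the counts were brain Hmgn2 knockout 1, brain double knockout 7, liver double knockout 11, thymus Hmgn2 knockout 820, thymus double knockout 12 and Hmgn2 knockout average 26. Without the 2 spleen libraries against their labels they were spleen Hmgn2 knockout 1, spleen double knockout 7 and Hmgn2 knockout organ difference 1, without arrays outside the fence brain difference 0, liver Hmgn2 knockout 2 and liver difference 4, and without both spleen Hmgn2 knockout 1, spleen double knockout 6 and spleen difference 1. Called lists with an estimated correlation were brain Hmgn2 knockout 0, brain double knockout 0, liver Hmgn2 knockout 0, liver double knockout 1, spleen Hmgn2 knockout 0, spleen double knockout 0, thymus Hmgn2 knockout 0 and thymus double knockout 1, and without arrays outside the fence brain Hmgn2 knockout 8, brain double knockout 5 and spleen Hmgn2 knockout 6. Leaving out an array or mouse in turn gave these ranges: double knockout average 20 to 38, Hmgn2 knockout average 3 to 11, double knockout organ difference 5 to 1.1e+02 (rounded), Hmgn2 knockout organ difference 0 to 27, brain double knockout 7 to 18, brain Hmgn2 knockout 1 to 3, brain difference 0 to 4, liver double knockout 11 to 30, liver Hmgn2 knockout 1 to 3, liver difference 1 to 6, spleen double knockout 0 to 1, spleen Hmgn2 knockout 0 to 1, spleen difference 0 to 1, thymus double knockout 14 to 29, thymus Hmgn2 knockout 771 to 2301 and thymus difference 30 to 898. Of the 16 thymus arrays, 14 moved the count of differences between mutants when left out, and the Hmgn2 knockout average was moved by mice 1, 2 and 3 of both its groups and the double knockout average by wild-type mouse 1. Array signal over background limits genes near the detection threshold.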

Other observations

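All tests in this part were set before their results were seen, except that groupings balanced by genotype were looked at separately afterwards.

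Whether other groupings of the same arrays give as many genes was counted for each comparison. With 4 arrays against 4 there are 35 groupings, and 100 were drawn for differences between mutants. The real grouping gave the most genes for the double knockout in the brain, where 13 genes passed and other groupings gave at most 1. It also did so for the double knockout in the liver (24 and 0) and the thymus (21 and 2). The same was seen for its average over organs (32 and 15), its differences between organs (17 and 1) and the Hmgn2 knockout thymus (1405 and 249). In each, 1 of the 35 groupings, the real one, gave as many, or 2.86 percent. That is the smallest share this tally can give, and it was not adjusted over the comparisons, so chance is made less likely but not excluded. Hmgn2 itself is among the genes counted within each organ. For the difference between mutants in the thymus, 3 of 100 groupings gave 157 genes or more, at most 600.

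By this tally alone, chance cannot be excluded for the number of genes called in the Hmgn2 knockout in the brain, where 6 of 35 groupings gave 2 genes or more, in the liver (5 of 35 for 1 gene) or on average over the organs (13 of 35 for 5 genes), with at most 364, 114 and 210 genes in other groupings. The tally concerns the number of genes and not Hmgn2 itself, the only gene called in the liver (adjusted p = 1.49e-12), nor single large changes such as Dhdds (1.5e-08) and Cap1 (1.1e-06) on average over the organs. The same holds for the difference between mutants in the brain (11 of 100 for 1 gene, at most 4) and the liver (8 of 100 for 2 genes, at most 5). Where 0 genes passed, every grouping gives as many by construction, so the count decides nothing about chance: this holds for the Hmgn2 knockout (35 of 35) and the double knockout (35 of 35) in the spleen, their difference there (100 of 100) and the differences between organs in the Hmgn2 knockout (35 of 35), with at most 480, 16, 600 and 437 genes in other groupings. Groupings with 2 arrays of each genotype on either side, which balance the genotypes, gave at most 19 genes in the brain, 114 in the liver and 480 in the spleen of cohort 1, which points to a structure of those samples other than genotype. In the thymus of cohort 1 such groupings gave at most 1 gene, and the groupings with the most genes, 249 and 214, kept 3 of the 4 arrays of each genotype together.

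Alleles of another mouse strain kept around a targeted locus were tested with the 100 annotated genes on each side of it. In the Hmgn2 knockout 9 of 71 such neighbours of Hmgn2 were called in any organ, against 1394 of 11146 other genes (one-sided Fisher exact p = 0.537). The thymus alone gave 9 and 1394 called genes, so its many calls set this result, which cannot decide about a kept flank. In the double knockout 2 of 114 neighbours of Hmgn2 or Hmgn1 were called, Dhdds beside Hmgn2 and Cbr3 beside Hmgn1, against 43 of 11102 other genes (one-sided Fisher exact p = 0.0764). In the brain of the Hmgn2 knockout Dhdds was the only gene called beside Hmgn2, and 1 of 57 neighbours against 0 of 9096 other genes gave a Fisher exact p = 0.00623, with an adjusted p = 0.0623 over 10 such tests. In the thymus of the double knockout, 2 of 98 neighbours, Cbr3 and Dhdds, against 18 of 8937 other genes gave an odds ratio of 10.3 (Fisher exact p = 0.0195, adjusted p = 0.0975). These tests cannot decide whether Dhdds and Cbr3 follow the genotype at the neighbouring locus. They do not reach genes beyond the 100 on each side. Cap1 and Rimkla, called in the Hmgn2 knockout thymus, are not among these neighbours, so linkage to Hmgn2 was not tested for them.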
